A study of Mus musculus with 4 samples.

How the data were processed

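Messenger RNA was sequenced from mouse bone marrow-derived macrophages, which are macrophages grown from bone marrow cells in culture with M-CSF. The cells were wild type (WT) or labelled as deficient in Phlpp1 (KO), and all were treated with interleukin-4 (IL-4) at 20 ng/ml for 12 h or 24 h. Per the labels' protocols, RNA was captured with mRNA beads and libraries were made with the VAHTS Universal V6 kit, and the labels do not say whether strand was kept. Each of the combinations of genotype and time had 1 library, so there were 4 libraries and no replicates. The labels do not say whether the libraries came from separate animals or cultures. Groups came from the sample labels, 1 of which spells the deficient genotype differently from the other.

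The authors deposited 1 table with whole-number counts and FPKM values per gene symbol and library. Per the submitters' processing notes, HISAT2, StringTie 1.3.0, edgeR and the mm10 mouse genome were used. Their roles and order, the counting tool and the annotation release are not given in the sources used here. The deposited FPKM values carried no scaling beyond gene length and library total: for genes with counts in all libraries, the count divided by the FPKM differed between libraries by the ratio of the libraries' total counts, with a largest relative deviation of 1.01e-13. FPKM values were used for that check alone. Every value below was computed from the counts. The table had 14936 genes, each with at least 1 count over the 4 libraries. Of these, 14488 symbols matched a GENCODE M21 gene name, and positions are given on GRCm38 (mm10) from that annotation. Copies of a gene that share sequence, overlapping genes and antisense partners cannot be told apart where the counting could split or merge their reads. This applies to Eif3j2, Rnaset2a, Cd209f, Cd209g, Rnase2a, Ear2, Mgl2, Clec10a and Ifit3, whose values are therefore uncertain. Gene-level counts do not show whether an exon of Phlpp1 is missing.

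Counts were scaled with the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3 and expressed as CPM, the scaled count relative to the library total. A ratio between 2 libraries is log2 of the first CPM plus 1 over the second CPM plus 1. The pseudocount of 1 understates the ratio of genes with low counts. A gene was measured in a ratio with at least 1 CPM in at least 1 of the 2 libraries. A ratio of at least 1 on the log2 scale, in either direction, passed a rule of size, which is not a test. With 1 library per group these ratios have no replicate check and no p-value. Folds of single genes between 2 libraries are given without the pseudocount, with exact 95% intervals from the binomial distribution of the 2 counts, and these compare the libraries, not the conditions. Such intervals cover counting error only, since the reads carried no molecular identifiers. A count of 0 was treated as up to 3 counts in that library, which is 0.0727 CPM in the library labelled WT at 12 h and 0.083 CPM in that labelled WT at 24 h.

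The tests were edgeR's quasi-likelihood tests of genotype and of time in an additive model (genotype plus time) over the 4 libraries, two-sided, with Benjamini-Hochberg adjustment over 10993 genes with at least 1 CPM in at least 2 libraries. The model leaves 1 residual degree of freedom, which holds the genotype-by-time difference together with noise. Its p-values therefore measure only the spread between these libraries, which may be technical. The common dispersion was 0.00602, a coefficient of variation of 7.76%. Genes with an adjusted p under 0.05 are called. The standard error (SE) of a log2 fold is its size divided by the square root of its F statistic. In counts simulated for genotype across both times with a dispersion of 0.006, this step was run on 10973 genes. It recovered 52 of 65 genes changed 1.5-fold, 64 of 65 changed 2-fold and 65 of 65 changed 4-fold, with 8 calls among 10778 unchanged genes. Agreement between ratios that share no library was described by Pearson's r and Spearman's rho across genes, which are not independent replicates. Shared genes were set beside the number that independent lists of the same sizes would share.

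There were 29 gene lists fixed before the data were examined, with 628 entries, of which 594 were in the table, 2 of them under a newer symbol. Of these lists, 1 is not reported here, nor is 1 gene that the naming rule below takes. The others cover the IL-4 response, NF-kB inflammation, type I interferon, FoxO targets, PI3K-AKT and PHLPP, cholesterol synthesis, LXR and lipid handling, fatty acid oxidation, oxidative phosphorylation, glycolysis and hypoxia, cell cycle, lysosome, MHC class II, extracellular matrix, ATF4 stress response, NRF2, immediate early genes and heat shock, and genes near Phlpp1. The lists of sex-linked and substrain genes and of mitochondrially encoded transcripts, and marker lists of macrophages, neutrophils, mast cells with basophils and eosinophils, lymphocytes, erythroid cells with megakaryocytes, stromal cells, dendritic cells and osteoclasts complete them. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 10 bins, as a percentile that describes these libraries. On simulated ratios over 11240 genes, 1 of 40 lists with no shift and 40 of 40 lists shifted by 0.5 fell outside the central 95% of random lists. The simulated ratios were independent between genes. These runs therefore do not show how often lists of co-regulated genes reach extreme percentiles, nor the power for smaller shifts. List members called in the additive model were counted after adjustment over all genes and adjusted over the list alone. Some genes are in more than 1 list and are counted in each. Examples are Ccl22 (IL-4 response and dendritic cells) and Tnfrsf11a (osteoclasts and genes near Phlpp1).

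Genes named in the text were chosen by a rule fixed before the data were examined. It takes Phlpp1 and Phlpp2, and the 10 genes higher and 10 lower for genotype by the smaller of the ratios at 12 h and 24 h, among genes past the rule of size in the same direction at both times with at least 5 CPM. It adds 5 in each direction at each time with at least 10 CPM, and 10 in each direction for time by the smaller of the ratios in WT and KO, with at least 5 CPM. It also takes up to 5 genes in each direction with opposite genotype ratios past the rule of size, and none met this. From each list it takes members past the rule of size at both times in 1 direction, or otherwise up to the 4 members with the highest mean, and any other list member may be given as a value. Predicted genes, pseudogenes, ribosomal protein genes and immune receptor segments, recognised by their symbols, were left out of the rankings. No filter on biotype was applied.

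The alternatives fixed before the data were examined were a pseudocount of 0.1 or 5, no filter or a filter at 5 CPM, median-of-ratios scaling, DESeq2 1.42.0 with the same model, and a model without the other factor. Leaving out each library, leaving out genes near Phlpp1 and the alternatives for the difference between times were chosen after seeing the data. The additive model leaves no residual degree of freedom with 3 libraries, so each fit with 1 library left out also left the other factor out of the model. The groups are then unequal over the other factor, so a change of a gene or list with that factor enters the fold. Clustering of calls along the genome was tested with 10000 circular shifts of the gene order and with 1000 shuffles of the calls. The shift test, run on simulated calls over 10819 genes, gave a p under 0.05 in 0 of 20 runs with random calls and 20 of 20 runs with 15 of 60 calls placed near Phlpp1. In the data 7 of 153 calls of at least 2-fold, Phlpp1 aside, lay there. The simulated cluster was far stronger, so these runs do not show the test's power at the size seen. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.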

Results

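The series set macrophages labelled Phlpp1-deficient against wild-type macrophages after 12 h and 24 h of IL-4, a cytokine that drives alternative activation. Phlpp1 encodes a protein phosphatase that removes an activating phosphate from the kinase AKT. Expression of 14936 genes was counted in 4 libraries, 1 for each genotype at each time. Total counts were 41770309 in the library labelled WT at 12 h, 39864159 in KO at 12 h, 37155457 in WT at 24 h and 36707999 in KO at 24 h. Between 13682 and 13814 genes had at least 1 count in a library. The 10 most abundant genes took 15.6% to 18.1% of the counts. The most abundant gene was Ctsd, a lysosomal protease, in the libraries labelled WT and Psap, the precursor of lysosomal activator proteins, in those labelled KO.

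Phlpp1 (chromosome 1, 106171752 to 106394250) was examined first, since it bears on the labels. It went against them: it had 1751 counts in the library labelled KO at 12 h and 2333 in that labelled KO at 24 h, beside 490 in the library labelled WT at 12 h and 564 in that labelled WT at 24 h. Scaled for depth, Phlpp1 stood at 42.9 and 62.6 CPM in the libraries labelled KO and at 11.9 and 15.6 CPM in those labelled WT. The library labelled KO was 3.61-fold higher at 12 h (exact 95% counting interval 3.26 to 4.0) and 4.01-fold higher at 24 h (3.66 to 4.41). In the additive model Phlpp1 was higher in the libraries labelled KO by 1.93 on the log2 scale (SE 0.10, edgeR adjusted p = 3.28e-14) and higher at 24 h than at 12 h by 0.48 (SE 0.10, adjusted p = 0.00624). Its paralog Phlpp2 stood between 9.74 and 11.4 CPM in the 4 libraries and was not called for genotype (log2 0.03, SE 0.16, adjusted p = 0.959). Each direction below is therefore that of the labels as given, and which libraries lacked Phlpp1 protein is not shown by these counts.

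**Figure D1:**
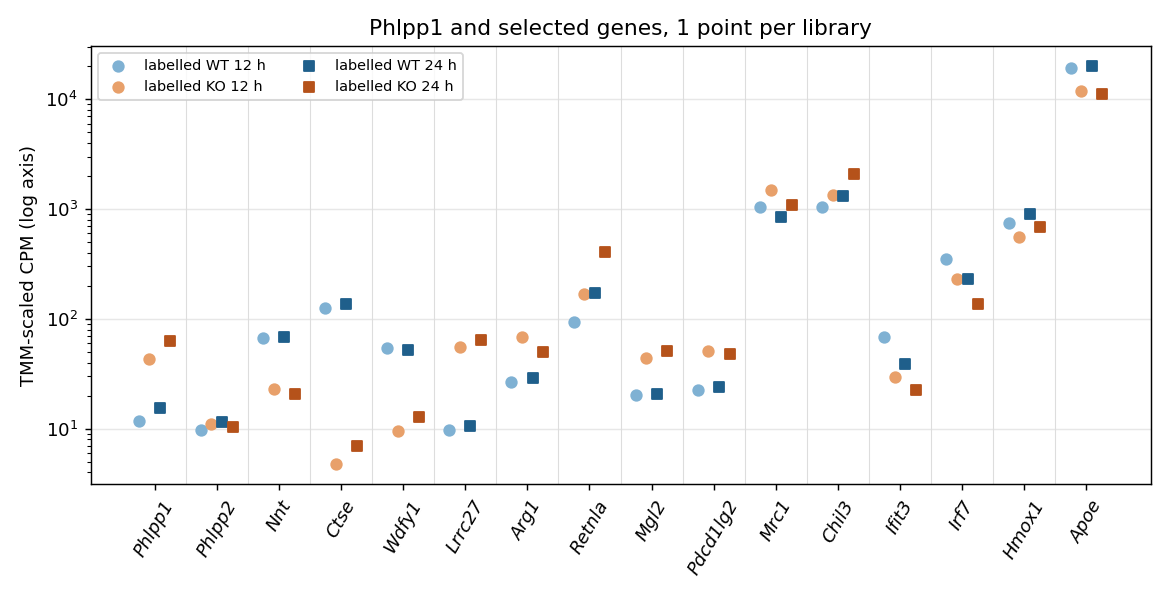
TMM-scaled CPM on a log axis for Phlpp1 and 15 other genes named in the text, with 1 point per library: circles for 12 h and squares for 24 h of IL-4, blue for libraries labelled WT and orange for libraries labelled KO. Phlpp1 stood at 42.9 and 62.6 CPM in the libraries labelled KO and at 11.9 and 15.6 CPM in those labelled WT, while Nnt was lower in both libraries labelled KO.

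Genes of the IL-4 response were higher in the libraries labelled KO, across both times. Of 34 members tested, 27 were called higher and 2 lower (29 and 3 adjusted over the list alone), and the list's median log2 ratio over both times was 0.57, above all 10000 random lists (percentile 100). Mgl2, a macrophage lectin, was higher by 1.21 (SE 0.10, edgeR adjusted p = 3.57e-10), Pdcd1lg2, which encodes the checkpoint ligand PD-L2, by 1.09, and Arg1, the arginase of alternatively activated macrophages, by 1.08. Retnla, a secreted marker of IL-4 activation, was higher by 1.05, with 93.0 and 172 CPM in the libraries labelled WT and 167 and 406 CPM in those labelled KO at 12 h and 24 h. Smaller differences in the same direction were called for the mannose receptor gene Mrc1 (0.45), the chitinase-like gene Chil3 (0.50) and the transcription factor genes Irf4 (0.70) and Egr2 (0.37). Against the list, F13a1, a coagulation factor subunit, was lower by log2 -1.47 (SE 0.14, adjusted p = 9.80e-09) and the transglutaminase gene Tgm2 by log2 -0.26. With time left out of the model, 12 members were called higher and 1 lower over all 4 libraries. With 1 library left out as well, 10 members were called higher without WT at 12 h, 18 without KO at 12 h, 9 without WT at 24 h and 19 without KO at 24 h, and 0, 2, 1 and 2 were called lower in that order. DESeq2 on all libraries called 23 higher and 2 lower.

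The medians of the type I interferon, NRF2 and macrophage identity lists were below 0 for the libraries labelled KO over WT. In the type I interferon list 11 of 28 members were called lower and 1 higher (21 and 1 adjusted over the list alone), with a median log2 ratio of -0.23, below all random lists. Ifit3, an antiviral effector, was lower by log2 -1.01, Irf7, the transcription factor that amplifies interferon production, by log2 -0.68 (SE 0.07, edgeR adjusted p = 1.68e-08), and the exception was Ifi44, higher by 0.49. Of 17 NRF2 targets, 12 were called lower and 0 higher (13 and 0 adjusted over the list alone), including Hmox1, which degrades heme (log2 -0.40, SE 0.06, adjusted p = 1.20e-05), and Gclm, of glutathione synthesis (log2 -0.53). Among macrophage identity genes 8 of 18 were called lower and 0 higher (9 and 0 adjusted over the list alone), with Fcgr1 (log2 -0.98) and Lyz2 (log2 -0.37) as examples. Apoe, which carries lipids and is an LXR target, stood at 19063 and 20086 CPM in the libraries labelled WT and at 11951 and 11087 CPM in those labelled KO (log2 -0.77, SE 0.05, adjusted p = 3.46e-12), and 6 of 26 members of the LXR list were called lower and 2 higher (8 and 6 adjusted over the list alone). Fits of 3 libraries also left out time. With WT at 12 h, KO at 12 h, WT at 24 h and KO at 24 h left out in turn, lower calls were 1, 10, 7 and 3 for type I interferon. In the same order they were 2, 1, 0 and 10 for NRF2, 2, 5, 2 and 5 for macrophage identity and 1, 3, 1 and 4 for LXR targets. Higher calls were 1, 0, 0 and 1 for type I interferon, 0, 1, 0 and 0 for macrophage identity and 0 each for NRF2 and LXR targets. Part of the type I interferon list fell and part of the NRF2 list rose with time, as given below, and such changes enter these folds. The counts of these fits therefore do not show dependence on a single library. DESeq2 on all libraries called 5 type I interferon genes lower and 1 higher, 9 NRF2 targets and 6 macrophage identity genes lower, and 4 LXR targets lower and 1 higher.

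Markers of other cell types differed between the genotypes too. Stromal and fibroblast markers were called higher in the libraries labelled KO for 13 of 15 members and lower for 0 (13 and 0 adjusted over the list alone), with a median log2 ratio of 0.67, above all random lists. Sparc, a matrix protein gene, was higher by 0.88 (SE 0.11, edgeR adjusted p = 6.44e-07) and the collagen gene Col1a2 by 0.71, at levels of 15.5 to 36.8 CPM. Bgn, the proteoglycan gene with the highest mean of the list, was higher by 0.61, at 30.5 to 57.5 CPM. Together the stromal markers took 0.0131% and 0.0155% of the counts in the libraries labelled WT and 0.0226% and 0.0256% in those labelled KO, at 12 h and 24 h. Neutrophil and granulocyte precursor markers were called lower for 7 of 15 members and higher for 0 (7 and 0 adjusted over the list alone), such as Ngp (log2 -0.50) and S100a9 (log2 -0.41). Of 5 erythroid and megakaryocyte markers tested, 3 were lower (4 adjusted over the list alone), led by Ppbp (log2 -0.66) and Pf4 (log2 -0.54), both also made by macrophages. Osteoclast markers were called higher for 4 of 9 members (5 adjusted over the list alone), among them Dcstamp, needed for cell fusion (0.93), and Atp6v0d2 (0.27). Cell cycle genes were called higher for 7 of 37 members and lower for 0 (11 and 0 adjusted over the list alone), with Mcm6, of the replicative helicase, higher by 1.57 and Mki67 by 0.42. The list's median log2 ratio over both times was 0.33, above all random lists, with 34 of 37 members above 0. The helicase genes Mcm2, Mcm3, Mcm4, Mcm5 and Mcm7 were not called. Fits of 3 libraries also left out time. With WT at 12 h, KO at 12 h, WT at 24 h and KO at 24 h left out in turn, higher calls were 1, 7, 4 and 8 for stromal markers, 2, 2, 1 and 1 for cell cycle genes and 0, 3, 1 and 1 for osteoclast markers. Lower calls were 1, 5, 2 and 2 for neutrophil markers and 1, 2, 0 and 1 for erythroid and megakaryocyte markers. DESeq2 on all libraries called 7 stromal markers, 3 osteoclast markers and 1 cell cycle gene higher, and 5 neutrophil and 2 erythroid and megakaryocyte markers lower.

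Over all genes, 459 were called higher and 587 lower in the libraries labelled KO across both times, of 10993 tested by edgeR, and 87 and 74 of these differed at least 2-fold. The lower genes were led by Ctse, an intracellular aspartic protease (log2 -4.51, SE 0.11, adjusted p = 5.20e-23), which stood at 126 and 136 CPM in the libraries labelled WT and at 4.73 and 6.92 CPM in those labelled KO at 12 h and 24 h. The naming rule ranks genes of at least 5 CPM by the smaller of the ratios at 12 h and 24 h, not by these folds. It also took Jchain, the joining chain of polymeric immunoglobulins (log2 -3.01), and the lectin genes Cd209g (log2 -3.15) and Cd209f (log2 -2.29). Further genes it took were Wdfy1, an adaptor for Toll-like receptors (log2 -2.25), Cers4, a ceramide synthase (log2 -2.60), and Itgad, an integrin chain (log2 -1.75). Slc13a3, a dicarboxylate transporter (log2 -1.56), and Id3, an inhibitor of transcription factors (log2 -1.45), were among them too. Nnt, a mitochondrial transhydrogenase that carries a deletion in the C57BL/6J substrain, was lower by log2 -1.62 (SE 0.09, adjusted p = 1.13e-13), from 66.8 and 68.0 CPM to 22.9 and 20.8 CPM. The higher genes included Lrrc27 (2.56, SE 0.10, adjusted p = 4.08e-17), Rbp4, a retinol carrier (2.15), Eif3j2 (1.96), Emp2 (1.81), Tenm4 (1.63), Lrrc32, which presents latent TGF-beta (1.58), Hgsnat, a lysosomal acetyltransferase (1.51), and Tmem26 (1.43). Of the 1046 called genes, 1045 differed in the same direction at both times, and the other, Gvin3, had a log2 ratio of -1.17 at 12 h and 0.01 at 24 h. The model favours this by construction, since a gene whose ratios disagree has a larger residual and is less often called. With time left out of the model, the number called for genotype across both times was 259, and with 1 library left out as well it was 179 without the library labelled WT at 12 h, 576 without KO at 12 h, 146 without WT at 24 h and 564 without KO at 24 h, and DESeq2 called 219 higher and 297 lower.

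Several lists had no member, or members in both directions, called for genotype across both times. Of 24 cholesterol synthesis genes, 34 oxidative phosphorylation genes and 6 MHC class II genes tested by edgeR, 0 were called (0 adjusted over the list alone), and DESeq2 called 0 too. The cholesterol synthesis gene Mvk was called lower with no filter, with a minimum of 5 CPM and with median-of-ratios scaling, and the MHC class II gene Cd74 was called lower with no filter. Without KO at 24 h and without time in the model, Cd74 was called lower and the oxidative phosphorylation gene Uqcrfs1 higher. At an unadjusted p under 0.05, 2288 of all 10993 genes passed for genotype. A genotype ratio that changes with time enters the model's residual, so 0 calls do not exclude a difference at a single time. The MHC class II median was log2 -0.13 at 12 h and 0.14 at 24 h (percentiles 4.3 and 97.93 of random lists). That of oxidative phosphorylation was 0.05 and -0.04 (percentiles 98.82 and 26.64). The cholesterol synthesis median lay inside the central 95% of random lists at both times. Glycolysis and hypoxia genes were called in both directions, with 3 of 28 higher, such as Bnip3 (0.65), and 3 lower, such as Vegfa (log2 -0.59), with 4 and 5 adjusted over the list alone. Among PI3K-AKT and PHLPP genes, the called members were Phlpp1 and the kinase gene Jak3 (0.55), both higher, and Inpp5d, an inositol phosphatase (log2 -0.22), of 29 tested (2 higher and 1 lower adjusted over the list alone). Of 20 FoxO targets, 2 were higher and 2 lower, with Txnip at 0.29 and S1pr1 at log2 -0.76 (2 and 2 adjusted over the list alone). In the NF-kB list 4 of 25 were higher, including the chemokine genes Ccl2 (0.94) and Ccl7 (0.85), and Nfkbiz was lower (log2 -1.06), with 4 and 1 adjusted over the list alone. Fits of 3 libraries also left out time. With WT at 12 h, KO at 12 h, WT at 24 h and KO at 24 h left out in turn, higher calls were 0, 1, 0 and 2 for glycolysis and hypoxia, 2, 1, 1 and 2 for NF-kB, 1, 2, 1 and 2 for PI3K-AKT and 0, 1, 0 and 0 for FoxO targets. Lower calls were 1, 2, 0 and 2 for glycolysis and hypoxia, 0, 1, 0 and 1 for NF-kB, 0 each for PI3K-AKT and 1, 1, 1 and 3 for FoxO targets. DESeq2 on all libraries called 1 glycolysis and hypoxia gene higher and 3 lower, 2 NF-kB genes higher and 1 lower, 1 PI3K-AKT gene (Phlpp1) higher, and 1 FoxO target in each direction.

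Lysosome and phagocytosis genes were lower in the libraries labelled KO by a small median, log2 -0.10 over both times (percentile 0.31 of random lists). Of 28 members 7 were called lower and 0 higher by edgeR (11 and 0 adjusted over the list alone), among them the scavenger receptor genes Stab1 (log2 -0.71) and Marco (log2 -0.59) and the receptor gene Mertk, for apoptotic cells (log2 -0.33). In the extracellular matrix list 5 of 22 were lower, among them Spp1 (log2 -0.43), and 2 higher, with the collagenase gene Mmp13 at 0.79 (6 and 2 adjusted over the list alone). The serine synthesis genes Psat1 and Phgdh were the 2 of 19 ATF4 targets called, both higher (2 adjusted over the list alone). Of 20 fatty acid oxidation genes, Ppargc1b was higher (0.56) and Ucp2 lower (log2 -0.22), with 2 and 2 adjusted over the list alone. Among 17 immediate early and heat shock genes, 3 were higher (Ier3, Hsph1 and Hspd1) and 2 lower (Fos, log2 -0.74, and Dusp1, log2 -0.66), with 4 and 2 adjusted over the list alone. The mast cell, basophil and eosinophil genes Cpa3 (log2 -2.37) and Prss34 (log2 -2.11) were lower, of 7 tested (2 adjusted over the list alone). Of 4 dendritic cell markers Ccl22, which is also in the IL-4 list, was higher (0.65, with 1 adjusted over the list alone). In the list of sex-linked and substrain genes Nnt was the 1 of 5 called (1 adjusted over the list alone). Of 13 lymphocyte markers in the table, Cd79b alone reached 1 CPM, with 3.90 CPM at most, and mitochondrially encoded transcripts were not analysed here. Fits of 3 libraries also left out time. With WT at 12 h, KO at 12 h, WT at 24 h and KO at 24 h left out in turn, lower calls were 1, 3, 2 and 4 for lysosome and phagocytosis, 2, 3, 0 and 2 for extracellular matrix, 1, 2, 1 and 2 for immediate early genes and 0, 1, 0 and 2 for mast cell genes. Higher calls were 1, 0, 0 and 1 for extracellular matrix, 2, 2, 1 and 2 for ATF4 targets, 1, 2, 0 and 1 for immediate early genes and 0, 1, 0 and 0 for dendritic cell markers, and 0 each in both directions for fatty acid oxidation. DESeq2 on all libraries called 5 lysosome and phagocytosis genes lower, 3 extracellular matrix genes lower and 1 higher, 2 ATF4 targets higher, 2 immediate early genes lower and 1 higher, 1 mast cell gene lower, Nnt lower, and 0 fatty acid oxidation genes and dendritic cell markers.

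**Figure D2:**
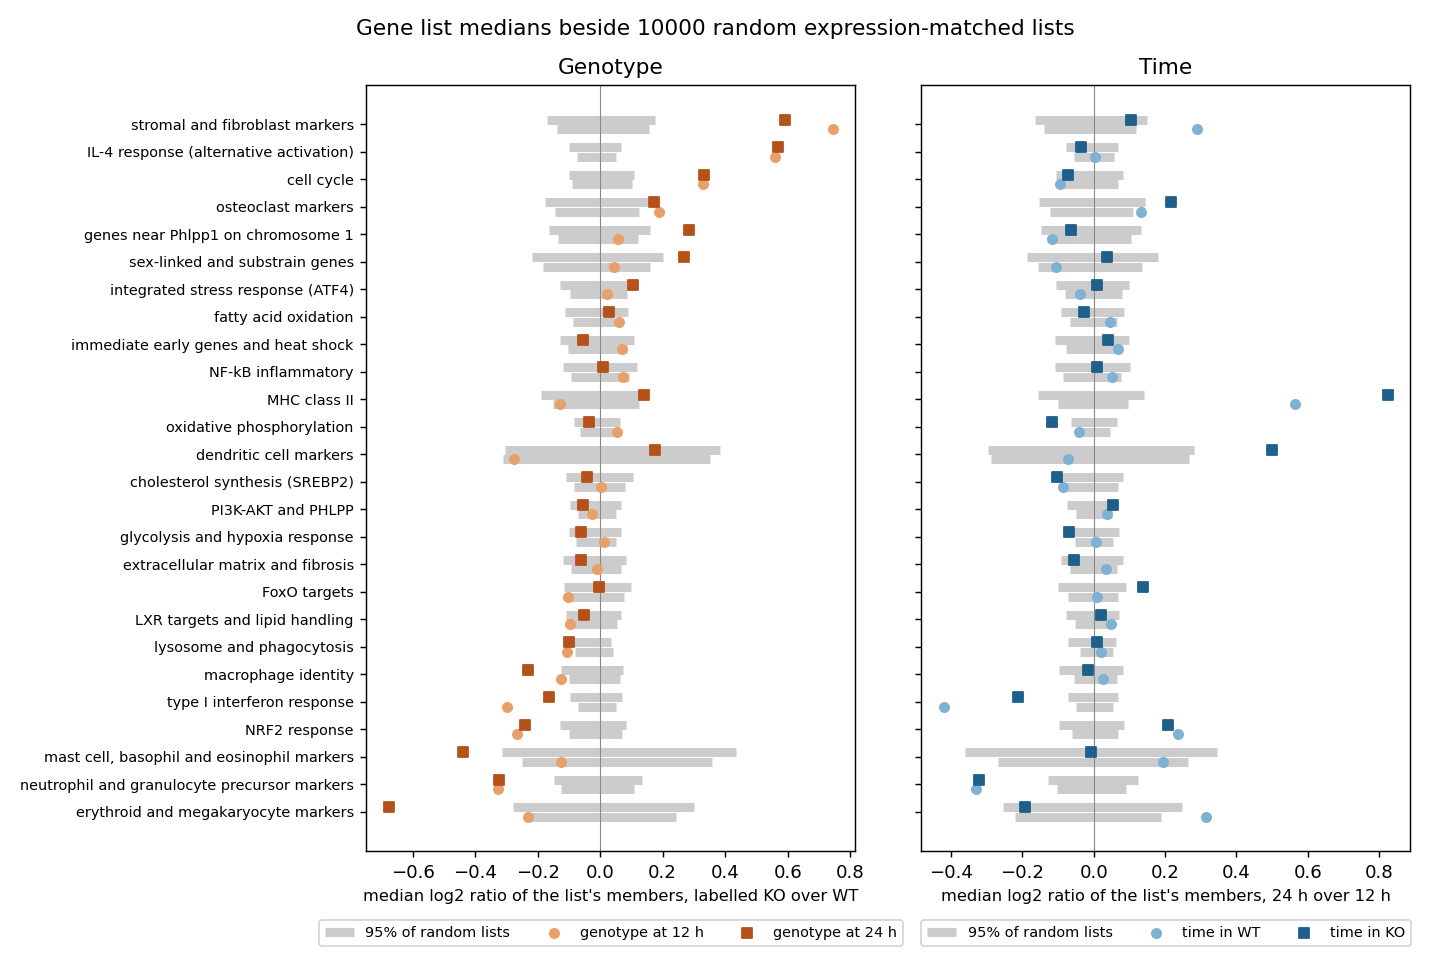
Median log2 ratio of the gene lists reported for genotype (left, labelled KO over WT at 12 h and 24 h) and for time (right, 24 h over 12 h in libraries labelled WT and KO), with grey bars for the central 95% of 10000 random lists matched on expression. The IL-4 response list stood at 0.56 at 12 h and 0.57 at 24 h for genotype, and MHC class II at 0.56 in WT and 0.83 in KO for time. Each median is over the members measured in that ratio, which can differ between ratios.

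Ctse, Wdfy1 and Mcm6, among the genes with the largest genotype differences named above, lay on chromosome 1 within 30 Mb of Phlpp1. In that window, 7 of 168 other genes with a position were called with at least a 2-fold difference, or 4.17%, beside 1.37% elsewhere. The 7 were Wdfy1, Mlph (1.47), Steap3 (log2 -1.14), Mcm6, the chemokine receptor gene Cxcr4 (log2 -1.26), Fam72a (log2 -1.45) and Ctse, of which Mlph, Steap3, Cxcr4 and Fam72a were named after their values were seen. The share was 0 of 14 genes within 10 Mb, 2.38% within 20 Mb and 2.29% within 50 Mb, and a stretch of chromosome 19 from 20 to 40 Mb held 7 of 77 (9.09%). Of calls of any size, 29 of the 168 genes within 30 Mb had one (17.3%), beside 9.35% elsewhere. Within 10 Mb it was 4 of 14, within 20 Mb 11.9% and within 50 Mb 13.1%. In the list of genes nearest to Phlpp1, 3 of 11 were higher, namely Serpinb2 (0.84), Tnfrsf11a (0.48) and Zcchc2 (0.34), and Serpinb8 was lower (log2 -0.51), with 4 and 1 adjusted over the list alone. Fits of 3 libraries also left out time. With WT at 12 h, KO at 12 h, WT at 24 h and KO at 24 h left out in turn, 0, 2, 0 and 2 of that list were called higher and 0, 1, 0 and 1 lower.

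**Figure D3:**
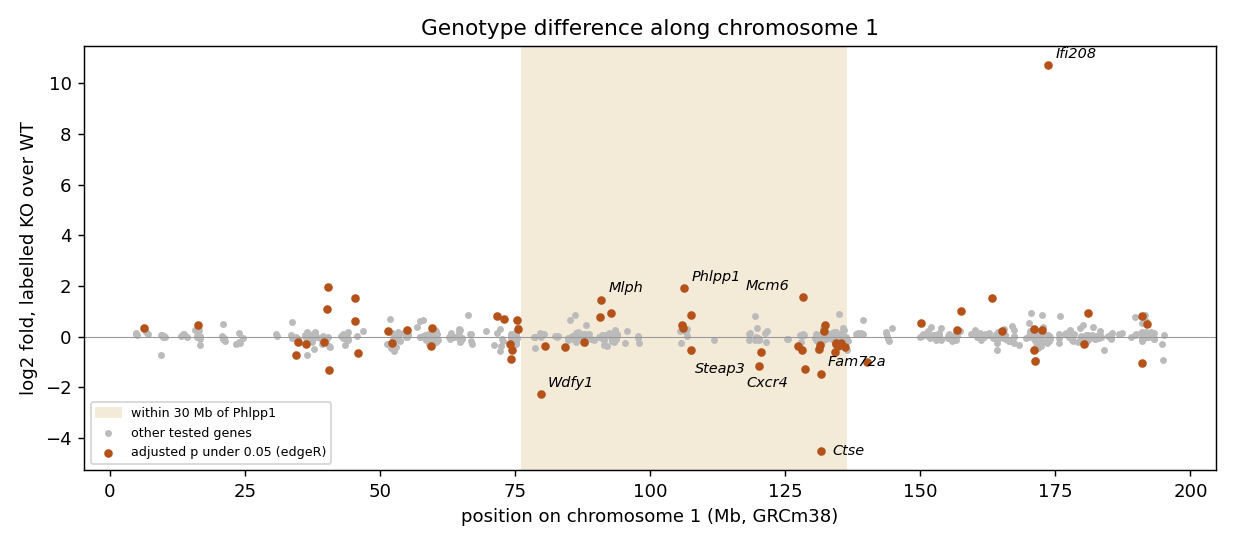
Log2 fold of the libraries labelled KO over WT (edgeR, both times) for tested genes along chromosome 1, with called genes in orange and the region within 30 Mb of Phlpp1 shaded. Called genes of at least 2-fold in the shaded region are named, from Ctse at -4.51 to Phlpp1 at 1.93, and the plotted fold of Ifi208, outside it, is no measured size, since both libraries labelled WT had 0 counts of it.

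At 12 h of IL-4 alone, Lrrc27, Phlpp1, Lrrc32, Rbp4 and Mcm6 were the most raised genes above 10 CPM in the library labelled KO, with log2 ratios of 2.41, 1.77, 1.61, 1.59 and 1.51. Ctse, Wdfy1, Jchain, Fabp7 and Cers4 were the most reduced, at log2 -4.47, -2.38, -2.28, -1.73 and -1.69. Fabp7 encodes a fatty acid binding protein. The IL-4 list had a median log2 ratio of 0.56, with 5 of 34 measured members past the rule of size upward and 1 downward, and the type I interferon list one of -0.30, with 0 of 28 upward and 1 downward. By the rule of size 65 genes were higher and 50 lower in KO at 12 h, of 11076 measured. These ratios rest on 1 library each and carry no test.

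At 24 h the most raised genes above 10 CPM were Lrrc27, Rbp4, Rnase2a, Phlpp1 and Hgsnat, with log2 ratios of 2.5, 2.15, 2.05, 1.94 and 1.63 for the library labelled KO over WT. Rnase2a belongs to the eosinophil-associated ribonuclease family and is in the IL-4 list, under its older symbol Ear11. Ctse, Cers4, Wdfy1, Rnaset2a and Itgad were the most reduced, at log2 -4.11, -2.53, -1.93, -1.85 and -1.82. The IL-4 list median was 0.57, with 3 of 35 measured members past the rule of size upward and 1 downward, and the type I interferon median was -0.16. By the rule of size 63 genes were higher and 53 lower at 24 h, of 11099 measured.

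The genotype ratios at both times, which share no library, went together across genes (Pearson's r = 0.536, Spearman's rho = 0.383, over 11240 genes). Lrrc27, Phlpp1, Rbp4 and Mcm6 were among 26 genes past the rule of size upward at both times, where independent lists would share 0.324. Ctse, Jchain, Wdfy1, Cers4 and Nnt were among 27 past it downward at both times, where independent lists would share 0.206. The rule of size was passed in opposite directions by 0 genes. The labels do not say whether both times of a genotype came from separate animals or cultures. A difference between animals or cultures could recur at both times, so this agreement is no replication of the genotype difference.

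**Figure D4:**
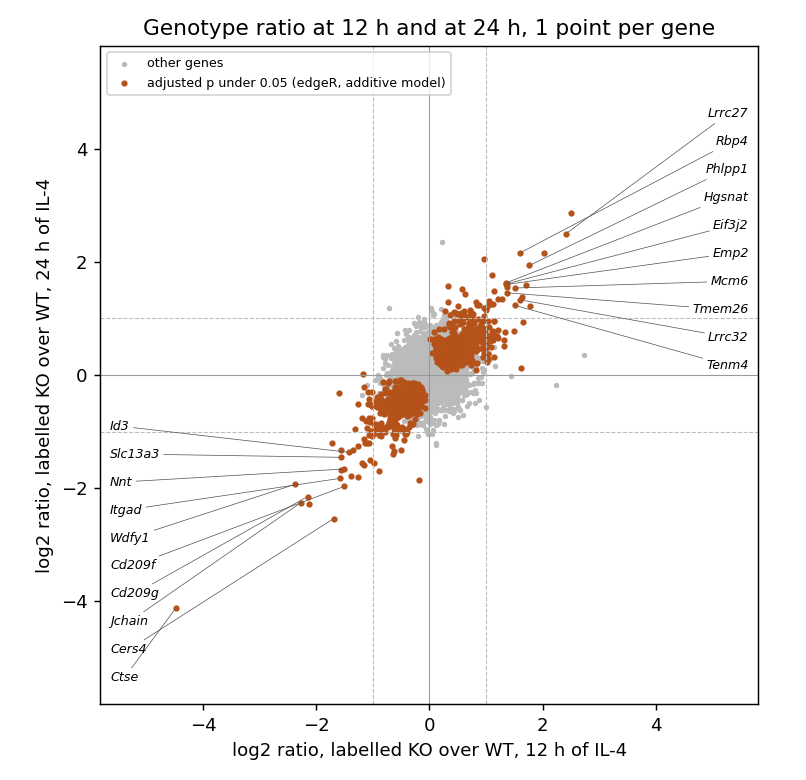
Log2 ratio of the library labelled KO over that labelled WT at 12 h of IL-4 (horizontal) and at 24 h (vertical), with 1 point per gene, genes called for genotype by the additive edgeR model in orange and dashed lines at the rule of size. Ctse lies at -4.47 and -4.11 and Lrrc27 at 2.41 and 2.5.

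The genotype ratio itself differed between the times, by the rule of size, for 71 of 11240 genes. It was larger at 24 h for 37 genes, among them Rnase2a (log2 ratio 0.97 at 12 h and 2.05 at 24 h), and smaller for 34, among them Rnaset2a (-0.18 and -1.85). Rnaset2a stood at 23.8 and 65.6 CPM in the libraries labelled WT and 20.9 and 17.5 CPM in those labelled KO at 12 h and 24 h, and has a near-identical copy, so its counts are uncertain. For MHC class II genes the median genotype ratio was -0.13 over 7 measured members at 12 h and 0.14 over 6 at 24 h. Cd74, which chaperones these molecules, had -0.42 and 0.09. No test of this difference exists with 1 library per group.

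From 12 h to 24 h of IL-4, across both genotypes, part of the MHC class II list was called higher and part of the type I interferon list lower. Of 6 MHC class II genes tested, 4 were called higher at 24 h and 0 lower (4 and 0 adjusted over the list alone). Cd74 rose by 0.83 on the log2 scale (SE 0.07, edgeR adjusted p = 9.74e-09), H2-Aa by 0.77, H2-Ab1 by 0.73 and H2-Eb1 by 0.70. In the type I interferon list 13 of 28 members were called lower, 0 higher and 15 neither (21 and 0 adjusted over the list alone), with Ifi27l2a at log2 -0.73 and Irf7 at log2 -0.69 (SE 0.07, adjusted p = 6.92e-08). Of 17 NRF2 targets 6 rose and 0 fell (12 and 0 adjusted over the list alone), including Gclm (0.58) and Hmox1 (0.29). Neutrophil and granulocyte precursor markers fell for 4 of 15 members and rose for 1 (6 and 1 adjusted over the list alone), with Mpo, the azurophil granule peroxidase, at log2 -0.81. Osteoclast markers rose for 3 of 9 members (4 adjusted over the list alone), among them Acp5, the tartrate-resistant phosphatase (0.48). Oxidative phosphorylation genes had 31 of 34 members below 0 (median -0.08, percentile 0.03) and cholesterol synthesis genes 18 of 24 (-0.08, 0.97). Cell cycle genes had 26 of 37 below 0 (-0.08, 1.8), and 0 members of these lists were called. PI3K-AKT genes had 19 of 29 above 0 (median 0.07, percentile 99.7), with 2 called higher (2 adjusted over the list alone). DESeq2 called 0 members of any of them for time. Stromal and dendritic cell markers had medians above 0 over both genotypes too. Stromal markers had 14 of 15 members above 0 (median 0.14, percentile 99.67) and 1 called higher (3 adjusted over the list alone). Dendritic cell markers had 5 of 6 above 0 (median 0.25, percentile 99.27), with 1 of 4 tested called higher (1 adjusted over the list alone). Their median was -0.07 over the 4 members measured in WT and 0.50 over the 6 measured in KO. The further members reached 1 CPM only in the library labelled KO at 24 h, which favours a higher ratio for them. They also enter the 5 of 6, and the medians in WT and KO cannot be compared. With genotype left out of the model edgeR called 0 members of these lists for time, with all 4 libraries and with any 1 of them left out as well, while DESeq2 with both factors called 4 MHC class II genes, 5 NRF2 targets, 1 osteoclast marker, 1 dendritic cell marker and 0 stromal markers higher and 8 type I interferon and 3 neutrophil genes lower.

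The IL-4 list split by time, with 6 of 34 members higher and 6 lower at 24 h (6 and 8 adjusted over the list alone). Retnla rose by 1.09 (SE 0.08, edgeR adjusted p = 1.35e-10), Ccl22, a chemokine gene, by 0.83 and Chil3 by 0.49, while the prostaglandin synthase gene Ptgs1 fell (log2 -0.96, SE 0.08, adjusted p = 1.96e-09), as did the VEGF receptor gene Flt1 (log2 -0.84) and Mrc1 (log2 -0.37). The largest rise was that of Rnase2a, itself a member of the IL-4 list (2.70, SE 0.18, edgeR adjusted p = 6.20e-11). It went from 1.87 to 8.49 CPM in WT and from 4.63 to 38.3 CPM in KO. Its family member Ear2 rose by 0.97 and Siglecf, an inhibitory lectin also found on eosinophils, by 1.11. Rbp4 (1.26), Scd1, a fatty acid desaturase (1.05), Fabp7 (1.03) and Hivep2 (0.81) rose too. With genotype out of the model, so that its difference entered the fold, Rbp4 stood at -0.25 without KO at 24 h and at 2.61 without KO at 12 h, neither of them called. The tetraspanning genes Ms4a4a (log2 -0.83), Ms4a4c (log2 -0.91) and Ms4a3 (log2 -0.81), the ribonuclease gene Rnase4 (log2 -0.87) and Qpct, a glutaminyl cyclase (log2 -0.77), fell. Over all genes, edgeR called 105 higher and 124 lower at 24 h of 10993 tested, and 11 and 4 of them changed at least 2-fold. All changed in the same direction in both genotypes, which the additive model favours by construction, as for genotype. With genotype left out of the model, with all libraries or with any 1 left out as well, 0 genes were called, with 367 of all genes at an unadjusted p under 0.05 in the first case and 267 to 599 in the others, and DESeq2 called 53 higher and 55 lower.

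**Figure D5:**
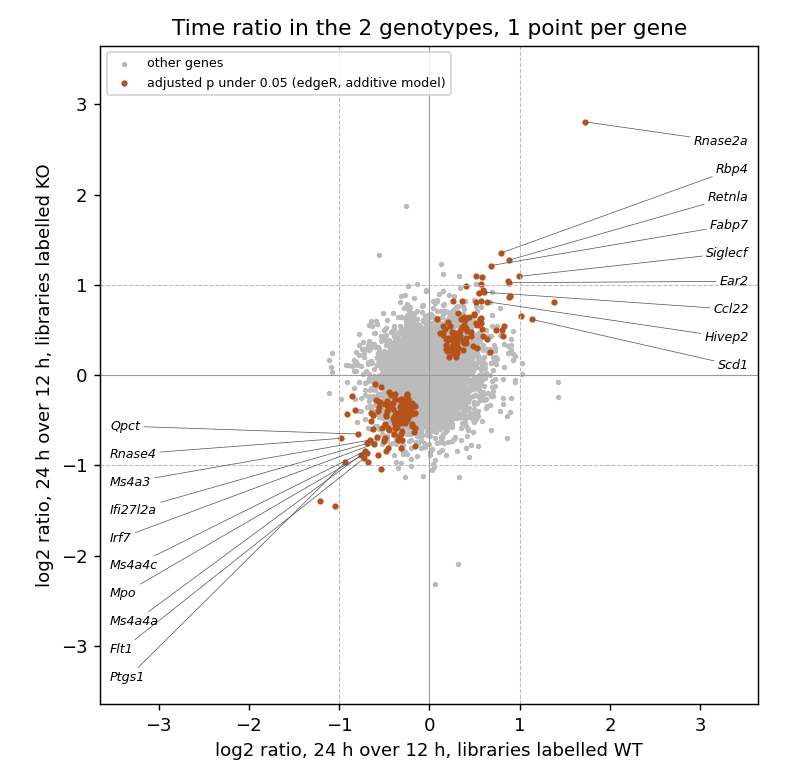
Log2 ratio of 24 h over 12 h of IL-4 in the libraries labelled WT (horizontal) and KO (vertical), with 1 point per gene, genes called for time by the additive edgeR model in orange and dashed lines at the rule of size. Rnase2a lies at 1.73 and 2.80 and Ptgs1 at -0.93 and -0.97.

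Within single genotypes, few genes passed the rule of size between the times. In the libraries labelled WT 8 genes were higher and 7 lower at 24 h of 11027 measured, and in those labelled KO 17 were higher and 12 lower of 11108. Rnase2a was the 1 gene higher in both genotypes, where independent lists would share 0.00899, and the 2 genes lower in both, where independent lists would share 0.00578, were Ctnnd2 and Lyzl4, named here after their values were seen. MHC class II genes had a median log2 ratio of 0.56 over 6 measured members in WT and 0.83 over 7 in KO. Type I interferon genes had one of -0.42 in WT and -0.21 in KO. The time ratios in both genotypes share no library and had a Pearson's r of 0.215 and a Spearman's rho of 0.182 over 11240 genes, and whether they differ between genotypes was not tested.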

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

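Leaving out each library, leaving out genes near Phlpp1 and every alternative for the difference between times were chosen only after the result was seen. Median-of-ratios scaling kept the direction and side of the threshold of the 151 folds of named genes in the model, with 1056 genes called for genotype across both times and 231 for time across both genotypes. Of the 229 genes called for time, 224 kept their call under it. No filter (1209 and 326) and a minimum of 5 CPM (996 and 260) kept these counts within 1.5 times. Leaving out genes within 30 Mb of Phlpp1 gave 1016 and 225. That was a recount of the same fit without those few genes, so the counts could hardly move and it is no check of the fit.

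DESeq2 called 516 genes for genotype across both times, all among edgeR's 1046, and 108 for time. For time it gave no adjusted p to 2132 of the 10993 genes, so its time calls cover fewer genes than edgeR's. With the other factor left out, 259 genes were called for genotype and 0 for time, where edgeR had 367 genes at an unadjusted p under 0.05. With 1 library left out as well as the other factor, the count for genotype ran from 146 (without WT at 24 h) to 576 (without KO at 12 h), with 179 without WT at 12 h and 564 without KO at 24 h, and that for time was 0 in each case. These fits change both choices, since the additive model leaves no residual degree of freedom with 3 libraries, and the lone library of a group is assumed to vary like the others. They are to be set beside the 259 and 0 of the fit without the other factor.

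With a pseudocount of 0.1 the rule of size took 304 genes for genotype at 12 h, 351 at 24 h, 141 for time in WT, 164 for time in KO and 342 for the difference between times. With a pseudocount of 5 it took 28, 33, 1, 5 and 3, and with a minimum of 5 CPM 74, 72, 6, 13 and 22. Pearson's r was 0.513 for the agreement of the genotype difference between times and 0.175 for the agreement of the time difference between genotypes with a pseudocount of 0.1, and 0.59 and 0.266 with a minimum of 5 CPM. Fewer genes near the minimum pass under a larger pseudocount or filter by construction.

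With a minimum of 5 CPM the median of mast cell, basophil and eosinophil markers, genotype at 24 h, turned to 0.062, from 1 member. In the fits without 1 library and the other factor, the genotype fold of Rnase2a ran from -0.15 without KO at 24 h to 3.52 without WT at 24 h, and that of Ptgs1 from -0.26 without KO at 12 h, by way of -0.09 without WT at 24 h, to 0.86 without WT at 12 h. The time fold of Rbp4 ran from -0.25 without KO at 24 h to 2.61 without KO at 12 h. The construction of these fits shows why the folds of Rnase2a and Rbp4 turned: with the other factor out of the model and unequal groups, the time change of Rnase2a entered its genotype fold and the genotype difference of Rbp4 its time fold. The same holds for Ptgs1, which fell with time. Of 108 list medians, 104 stayed the same with a pseudocount of 0.1 and 93 with a minimum of 5 CPM. Of the 151 folds of named genes in the model, 11 lost their call and 136 did not change with DESeq2, and the rest had no adjusted p there. With the other factor left out 48 lost it and 103 did not change. With the other factor left out, genotype calls were 12 higher in the IL-4 list, 5 higher in the stromal list and 1 higher in the cell cycle list, and 2 lower for type I interferon, 1 for NRF2 and 3 for macrophage identity. A pseudocount for the model and limma without a trend were not run, since the values were counts. Depth limits the genes near 1 CPM, where 3 counts make 0.0727 to 0.083 CPM.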

Other observations

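The uses of the values below as tests of an explanation were chosen only after the result was seen, except the tests of time calls near Phlpp1 and of pairs of calls elsewhere in the genome, although the correlation of the genotype ratios and the model fold of Phlpp1 were themselves planned results. The interferon-inducible gene Ifi208, on chromosome 1 but 67.4 Mb from Phlpp1, had 0 counts in both libraries labelled WT and 192 and 233 in those labelled KO at 12 h and 24 h. Against a floor of 3 counts per library it was at least 64.7-fold higher at 12 h and at least 75.3-fold higher at 24 h. Gene-level counts do not show whether its absence in the libraries labelled WT lies in expression or in how reads were assigned. Lrmda had 14 and 16 counts in the libraries labelled WT and 182 and 202 in those labelled KO. Both were named after their values were seen.

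Genes called for genotype and for time overlapped, with 114 in both lists where independent lists would share 21.8. Retnla and Chil3 were higher in the libraries labelled KO and rose with time, while Irf7 and Ifit3 were lower in them and fell with time. Flt1 was higher in the libraries labelled KO and fell with time, and Hmox1 and Gclm were lower in them and rose with time. Rnase2a and Ptgs1 were also in both lists, with genotype log2 ratios of 0.97 and 0.32 at 12 h and 2.05 and 0.28 at 24 h. In fits with 1 library and time left out, where their time changes enter, the genotype fold was -0.15 for Rnase2a without KO at 24 h, and -0.26 and -0.09 for Ptgs1 without KO at 12 h and without WT at 24 h. Both tests come from 1 fit and share its dispersion.

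Phlpp1 was higher, not lower, in the libraries labelled KO at both times. An exchange of labels within 1 time's pair is argued against by the correlation of the genotype ratios at 12 h and 24 h across genes (Pearson's r = 0.536), which such an exchange would make negative. Reads of Phlpp2 counted for Phlpp1 are argued against by the summed counts of both genes, still higher by 1.32 on the log2 scale at 12 h and 1.44 at 24 h. Labels exchanged at both times cannot be told apart from an allele that leaves transcript in place or raises it, since the fold of 1.93 goes with either and gene-level counts show no exon. A biological rise of a transcript that makes no protein stays open and may be a hypothesis for exon-level reads.

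Calls of at least 2-fold were denser within 30 Mb of Phlpp1 than elsewhere, as linked DNA of another strain may leave them in a gene-targeted line (one-sided circular-shift permutation p = 0.0348). That stays open, since windows of 10 Mb, 20 Mb and 50 Mb gave permutation p of 1, 0.323 and 0.209 (for calls of any size 0.0533, 0.275 and 0.0641, and 0.0117 within 30 Mb), and a stretch of chromosome 19 from 20 to 40 Mb was denser, with 7 of 77 genes (9.09%). Time calls did not gather in the window (p = 0.666), but only 3.51 were expected there, and time calls paired with neighbours elsewhere (permutation p = 0.011), so the bound set in advance was inadequate and neighbouring genes called together stay open. For segments of another strain elsewhere, the 146 calls of at least 2-fold outside the window made 35 pairs within 2 Mb where shuffled calls gave 32.8 on average (permutation p = 0.375), and all 996 calls there 1528 pairs against 1536 (p = 0.537), yet Nnt, which differs between C57BL/6 substrains, was lower by log2 -1.62, so they cannot be excluded. A biological effect of Phlpp1 on these genes was not tested.

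IL-4 response genes were higher in the libraries labelled KO. More stromal cells in those libraries are argued against as the whole cause: after 15 members that fibroblasts are known to express were left out, 18 of 19 members were above 0 with a median of 0.65, and the highest stromal marker, Bgn, stood at 57.5 CPM or less, with 0.0256% of the counts or less in all stromal markers together. A difference in scaling between the genotypes shifts all genes nearly alike, so it drops out of the list's excess over the median of all genes. The smallest excess, 0.56 over both times and both scalings, shows that the list was higher relative to other genes. It restates the list medians and is no separate test of scaling. A difference between single cultures rather than genotype cannot be told apart from genotype, with 1 library per genotype and time. A stronger IL-4 response in the cells labelled KO may be a hypothesis for replicate cultures with and without IL-4, with the direction of the labels itself open. Segments of another strain, left open above, were not tested as a cause for this list. Replicate cultures of the same lines would not separate them from the Phlpp1 allele. All libraries here had IL-4, so a stronger response cannot be told apart from a difference present without it.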
